A study of Mus musculus with 44 samples.

How the data were processed

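The 44 samples were PGC sorted by FACS from mouse embryos and from males after birth, and a male ESC line with an Oct4-GFP reporter. RNA was amplified and labelled with biotin, starting where possible from 300 ng, and hybridized to MouseRef-8 v2 beadchips. Groups were taken from the sample titles and stated ages and sexes, which gave 23 groups of 2 arrays each, except ESC and males at 14 dpp with 1 array.

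The deposited intensity table gives the mean bead brightness of 25697 probes on each array from BeadStudio 3.2, with no scaling between arrays. Beside each intensity column the deposited table gives a detection p-value, the share of negative control probes at least as bright. A further table from the authors holds log2 values, which the submitters' notes trace to RMA and lumi. Checked on the file, each of its columns has the same sorted values to within 0.0014 and the rank order of the deposited intensity (lowest rank correlation 1), as quantile normalization gives, with a median of 3.20. All comparisons used the deposited intensity values, and the authors' log2 values served as an alternative. The lowest correlation of an array between both scales was 0.992. No column was left without a sample.

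Intensities were background-corrected from the detection p-values and quantile-normalized with an offset of 16 (neqc, limma 3.58.1 in R 4.3.3). Probes were kept when detected with a detection p under 0.01 on at least 2 arrays, which left 16086. Symbols came from the probe annotation and were matched to RefSeq GRCm38.p6, which was used for gene names and chromosomes alone. Of all probes 23978 had 1 symbol, 0 had several and 1719 had none. Of those with a symbol, 23962 were matched by Entrez gene, 9 by accession and 7 kept the annotation's symbol, and 8 names were updated. Of the kept probes 15127 had a symbol. Where a gene had several such probes (2924 genes) the brightest was used, which gave 10935 genes, 381 of them on the X chromosome. Kit, Sycp3, Dmc1, Ddx3y, Zbtb16, Foxl2, Star and Lyz2, which were among the reference genes, did not pass these steps and were not used here.

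A linear model with 23 group means was fitted to all 44 arrays with limma, with 21 residual degrees of freedom and 3.63 prior degrees of freedom. Groups of 1 array were assumed to vary like the others. Each comparison was a contrast of group means tested two-sided with the moderated statistic, and p-values were adjusted by Benjamini-Hochberg within the comparison. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. The change of the sex difference over days was tested with the moderated F-test over 6 contrasts. A group with a gene detected on none of its arrays was taken as below the background, and the fold against it was computed to the lowest value of any detected probe on each array (or to the measured value where that was higher) and given as a bound.

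Gene lists of pluripotency, early germ cells, germline genes that gonadal germ cells switch on, meiotic axis and synaptonemal complex, meiotic recombination, oocytes, fetal male germ cells, the piRNA pathway, DNA methylation machinery, spermatogonia, spermatocytes, spermatids, mitosis, DNA replication, cyclin-dependent kinase inhibitors, apoptosis, glycolysis, mitochondrial respiration, imprinted genes, Y-linked genes, immediate early and heat shock genes, and markers of Sertoli, granulosa, steroidogenic, endothelial, mesenchymal, erythroid and macrophage cells were written by hand from general knowledge, and the X chromosome was added from the reference. Lists share members, such as Lefty1 and Nodal (pluripotency and fetal male germ cells), Ddx4 and Mael (gonadal germline genes and piRNA pathway) and Utf1, Sall4 and Lin28a (pluripotency and spermatogonia). Each list was tested against all other genes with camera in limma with a preset correlation of 0.01, and again with the estimated correlation, with adjustment over the lists of a comparison. A list passed at an adjusted p under 0.05 with the preset value.

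The genes named in the text follow a rule set with the lists. It takes the 10 largest rises and 10 largest falls (5 each way for single days) among called genes with a proper symbol whose arrays did not overlap between the compared groups. It adds up to 4 called members of a list with the largest change, a set of reference genes, and members of cell marker lists that passed. Only part of the genes the rule takes are printed.

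Overlap of the female and male changes at meiosis was tested by Fisher's exact test, two-sided. Alternatives were no background correction, normexp with an offset of 50, cyclic loess, median scaling, the authors' values, no filter, detection on at least 4 arrays, each probe on its own, no fold threshold, a variance trend with a robust prior, array weights, the replicate number as a block, the compared arrays alone, other days or groups, and leaving out each array in turn. Alternatives that leave out or replace the E16.5 female arrays, and those for the overlap at meiosis (E17.5 as the end day, or only genes detected on at least 1 compared array in both changes), were chosen after seeing the data. A difference between changes was given as a bound where a compared group lay below the background. Splits of the arrays were drawn at random, 100 with the real one, and whole groups were exchanged in all 64 and 10 possible ways, a choice made after the result was seen, and marker correlations were set against 10000 random lists of genes. The procedure was tested on simulated data with the spread of each group, in which 4-fold changes were called for 73.1% to 100% of changed genes, 8-fold for 98.5% to 100% and 2-fold for 25.4% to 56.7%. Of 200 unchanged lists per comparison 0 to 8 had p under 0.05. Genes were simulated independently of each other, so this count does not cover lists whose members vary together. Members of some marker lists did vary together on the real arrays, as the closing section gives. The count therefore does not show how often such a list would pass without a change. Figures were drawn with matplotlib 3.10.9 and tables written with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.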

Results

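Gene expression was measured in mouse primordial germ cells (PGC), the precursors of eggs and sperm, which had been sorted by FACS, and in a male embryonic stem cell (ESC) line that carries an Oct4-GFP reporter. Each of the 44 samples was hybridized to a MouseRef-8 v2 beadchip, and the samples formed 23 groups. There was 1 ESC array, and there were 2 arrays of E11.5 PGC, whose sex the labels leave undefined. Female and male PGC had 2 arrays each at each embryonic day from E12.5 to E18.5. Cells from males after birth, which the labels also call PGC, had 2 arrays each at 8, 10, 12, 16, 18 and 20 days post partum (dpp) and 1 array at 14 dpp. The series counts the duplicates as biological replicates, while its protocol allows biological or technical ones and no animals are named, so each p-value measures only the spread between these samples.

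Array brightness differed by stage. The upper quartile of probe intensity ran from 79.9 to 170.2 on the embryonic PGC arrays, was 323.6 for ESC and ran from 295.5 to 605.5 after birth. Between 24.9% and 49.3% of the probes were detected on embryonic PGC arrays, 38.4% in ESC and 42.1% to 46.1% after birth. The pair of E16.5 female arrays was the dimmest (79.9 and 82.4) and its replicates differed most, with a standard deviation of 0.667 log2 units. The E11.5 pair came next with 0.552, and postnatal pairs differed by 0.123 to 0.22. The number of arrays limits the precision of every value below.

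In what follows, a gene described as higher, lower, risen or fallen passed both an adjusted p threshold of 0.05 and a 2-fold threshold, and a value after ± is the standard error of the log2 difference. Where a compared group lay below the background, the fold is a bound, written "at least". Each gene list was fixed before the data were examined. The number of list members that passed when adjusted over the list alone was equal to the number over all genes unless it is given. Fewer genes were called in every comparison below without background correction or with an offset of 50 added to the intensities, apart from the test of sex by day, and those counts stand in the closing section.

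Which genes set PGC apart from pluripotent cells was asked by comparing the 15 embryonic PGC groups with the single ESC array. That array has no replicate, so its spread is taken from the other groups in every p-value against ESC, and it was brighter than every embryonic PGC array. Germline genes were higher in PGC, and genes of pluripotency, DNA replication and glycolysis were lower. Of 10 measured germline genes that germ cells switch on in the gonad, 7 were higher and 0 were lower (adjusted p = 1.40e-05). Among them, Mov10l1, a helicase of the piRNA pathway, was at least 35.4-fold higher, and Ddx4, a germ cell RNA helicase, was at least 9.2-fold higher on its brightest probe, with 1.37 and 0.11 on others. The bromodomain gene Brdt was at least 10.3-fold and the germ cell surface gene Tex101 at least 6.4-fold higher. Of 14 piRNA pathway genes, which guard the germline against transposons, 11 were higher and 1 was lower (adjusted p = 1.40e-06), with Tudor domain genes Tdrd7 (log2 difference 4.20 ± 0.21) and Tdrkh (4.16 ± 0.14) and the PIWI gene Piwil2 (3.76 ± 0.14). Of 11 meiotic recombination genes, 7 were higher and 0 lower (adjusted p = 5.37e-03, and adjusted p = 6.19e-02 with an estimated correlation). Spo11, which makes the meiotic double-strand breaks, was at least 23.4-fold higher, the crossover gene Msh4 at least 3.5-fold and Spata22 at least 4.9-fold. Other large rises were those of Pik3r3, a phosphoinositide kinase subunit (4.75 ± 0.14), Mageb4 (4.45 ± 0.17), the G protein gene Gnaz (at least 18.8-fold), Tex13b (at least 16.2-fold), the imprinted gene Dlk1 (at least 13.3-fold), Plcl2 (at least 11.3-fold) and the zinc finger gene Bnc1 (at least 9.2-fold). Among the genes named here the highest bound was that of Hba-a1, an alpha globin of red blood cells, at least 39.9-fold. The erythroid list as a whole did not pass (1 of 6 higher, adjusted p = 4.04e-01).

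Of 19 pluripotency genes, 18 were lower in PGC than in ESC and 0 were higher (adjusted p = 6.06e-13). Nanog differed by -5.47 ± 0.37, Tbx3 by -4.61 ± 0.35, Esrrb by -3.83 ± 0.43 and the DNA methyltransferase gene Dnmt3b by -3.70 ± 0.16. Smaller falls were those of the core factors Sox2 (-2.89 ± 0.37) and Pou5f1 (-2.03 ± 0.27). Of 5 genes of the DNA methylation machinery, 4 were lower (adjusted p = 4.23e-05), among them Dnmt3l, a cofactor of de novo methylation (-4.23 ± 0.44), and Uhrf1, which recruits the maintenance enzyme (-2.76 ± 0.19). The Dnmt3l value averages both sexes, which differed widely in this gene from E13.5 on, and does not describe each PGC group. DNA replication genes were lower for 9 of 13 (adjusted p = 8.41e-08), with the sliding clamp gene Pcna at -4.52 ± 0.41 and the licensing factor gene Cdc6 at -3.84 ± 0.25. Mitosis genes were lower for 6 of 9 (adjusted p = 7.71e-05), with Ccna2 at -1.83 ± 0.31 and Cdk1 at -1.73 ± 0.20. Glycolysis genes were lower for 10 of 12 (adjusted p = 7.01e-09), with Tpi1 at -3.77 ± 0.33, the glucose transporter gene Slc2a1 at -3.57 ± 0.16 and Ldha at -3.29 ± 0.19. The largest falls also took in the amino acid transporter gene Slc7a3 (-6.58 ± 0.36), the stress response factor Atf4 (-5.36 ± 0.35) and Chac1 (-5.28 ± 0.38), the heat shock gene Hspb1 (-5.34 ± 0.56) and Klf9 (-5.87 ± 0.39). The limma test called 3680 of 10935 genes, 1880 higher and 1800 lower in PGC. In each of the 15 groups 247 genes were at least 2-fold above ESC, of which 90 were not detected in ESC, and 518 genes were at least 2-fold below. Median scaling moved the median of all genes by -0.765 log2 and gave 533 higher and 4461 lower genes. With E11.5 alone against ESC, the direction turned for the mitosis list, for Spata22, for Tex101 and for Sox2. Of the 8 lists that passed, only 4 still passed at E11.5 alone, 3 lost their pass and 1 turned, while 2 others gained a pass. Recombination genes averaged 6.61 log2 in ESC, 6.75 at E11.5 and 10.22 in E15.5 females. The mean over 15 groups thus does not describe E11.5 PGC for every list.

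The step from E11.5 to E12.5, when germ cells settle in the gonad, was tested as the mean of female and male E12.5 cells (4 arrays) minus E11.5 (2 arrays). Germline and meiotic genes rose, and markers of blood and vessels fell. Taf7l, a germ cell subunit of the general transcription machinery, rose at least 1.9-fold and Tex11, a meiotic recombination gene on the X chromosome, rose by 1.94 ± 0.23. In all 4 of 10 gonadal germline genes rose and 0 fell (adjusted p = 1.35e-06). Of 7 genes of the meiotic axis, 5 rose and 0 fell (adjusted p = 1.80e-06), with the cohesin genes Rec8 (2.95 ± 0.29) and Smc1b (1.24 ± 0.25) and the axis gene Hormad2 (1.12 ± 0.25). This list averaged 6.61 log2 at E11.5, 8.51 in E12.5 females and 7.15 in E12.5 males, so its rise was mainly female. Meiotic recombination genes rose for 3 of 11 (adjusted p = 3.05e-04), with Spo11 at 1.18 ± 0.16, and 1 of 14 piRNA genes rose, Tdrd7 at 1.80 ± 0.18 (adjusted p = 6.23e-03 for the list). Further rises were those of the Wnt target Sp5 (2.69 ± 0.30), the elongation complex gene Ice2 (2.72 ± 0.42), the germ cell kinase gene Stk31 (2.28 ± 0.33), the Polycomb inhibitor gene Ezhip (2.15 ± 0.30) and Bnc1 (2.10 ± 0.18).

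All 6 erythroid markers were lower at E12.5 than at E11.5 (adjusted p = 7.70e-07, and adjusted p = 6.60e-02 with an estimated correlation), with the embryonic globin genes Hbb-bh1 at least 13.3-fold lower and Hba-x at -4.81 ± 0.75. Endothelial markers were lower for 3 of 7 (adjusted p = 5.35e-05), with Esam at least 3.4-fold and the receptor gene Tek at least 1.7-fold lower. Mesenchymal markers were lower for 3 of 10, or 4 adjusted over the list alone (adjusted p = 6.23e-03, and adjusted p = 2.60e-01 with an estimated correlation), with smooth muscle actin, Acta2, at least 13.9-fold lower on its brightest probe and at -1.40, -2.18 and -2.29 on others, the first of which did not pass. Imprinted genes were lower for 4 of 14, or 5 adjusted over the list alone (adjusted p = 1.07e-03, and adjusted p = 6.51e-02 with an estimated correlation). Of these, the growth regulator Grb10 fell by 1.73 ± 0.36, while Phlda2 (-1.92 ± 0.28) was higher than at E11.5 in E12.5 female cells alone, and Igf2 (-1.14 ± 0.36) lost its fall without E11.5 replicate 1. Of 12 glycolysis genes 1 fell, Pfkp at -1.31 ± 0.33 (adjusted p = 1.89e-05 for the list). The reference genes Ddx4 (0.92 ± 0.35), Dazl (0.66 ± 0.18) and Nanog (-0.46 ± 0.32) did not pass. Limma called 644 genes, 364 higher and 280 lower, and in simulated data with these spreads it called 146 unchanged genes. Median scaling gave 322 higher and 11 lower genes with a median shift of 0.154 log2, while no background correction gave 9 and 24 and an offset of 50 gave 19 and 36. The count ran from 278 without E11.5 replicate 1 to 1660 without E11.5 replicate 2, was 217 with array weights and was 0 by limma on the 6 compared arrays alone, where 1921 genes had an unadjusted p under 0.05.

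Female and male PGC were compared on each day to ask when their expression parts (2 arrays against 2 each day). At E12.5 meiotic axis genes were already higher in females, and fetal male germ cell genes and Sertoli markers were higher in males. Of 7 meiotic axis genes, 4 were higher in females and 0 lower (adjusted p = 1.78e-04, and adjusted p = 6.53e-02 with an estimated correlation), with Rec8 at 4.34 ± 0.34 and Stra8, which is needed for entry into meiosis, at least 1.9-fold. Gonadal germline genes were higher for 3 of 10 (adjusted p = 2.29e-03, and adjusted p = 6.53e-02 with an estimated correlation), with Taf7l at 2.68 ± 0.18. Largest in females were Phlda2 (5.92 ± 0.32), the homeobox gene Cdx2 (at least 22.1-fold), the transcription factor Gata2 (5.17 ± 0.26) and the peptide hormone gene Sct (4.77 ± 0.42). Of 14 imprinted genes, 3 were higher in females, Phlda2 and Igf2 (1.33 ± 0.42) among them, and 1 was lower, Mest (-1.87 ± 0.46), or 4 and 1 adjusted over the list alone (adjusted p = 2.68e-02, and adjusted p = 2.18e-01 with an estimated correlation). Of 8 fetal male germ cell genes, 5 were lower in females and 0 higher (adjusted p = 8.99e-09). The Nodal inhibitor genes Lefty2 and Lefty1 were at least 43.8-fold and at least 36.1-fold lower, and Nanos2, an RNA-binding regulator of male fate, differed by -3.03 ± 0.50. Spermatogonial genes were lower in females for 7 of 20 and higher for 1 (adjusted p = 2.29e-03), with Egr4, a transcription factor, at least 3.7-fold lower. Sertoli markers were lower in females for 6 of 13, or 7 adjusted over the list alone (adjusted p = 5.04e-06), with the cystatin gene Cst9 at least 13.9-fold and the ligand gene Dhh at least 3.7-fold lower. Pluripotency genes were lower for 4 of 19 (adjusted p = 2.44e-03), among them Nodal (-1.72 ± 0.25). Glycolysis genes were lower for 2 of 12 (adjusted p = 8.25e-03, and adjusted p = 1.85e-01 with an estimated correlation). Y-linked genes were lower for 2 of 5 (adjusted p = 2.29e-03), with Eif2s3y at least 13.4-fold lower. Of 381 genes of the X chromosome, 42 were higher in females and 8 lower, or 43 and 10 adjusted over the list alone (adjusted p = 6.86e-05). Limma called 966 genes, 567 higher and 399 lower in females, against 236 and 104 under median scaling, 460 with cyclic loess and 590 on the 4 compared arrays.

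At E13.5 limma called 2185 genes, 1188 higher and 997 lower in females. Meiotic axis genes were higher for 6 of 7 (adjusted p = 1.19e-06), with Rec8 at 4.38 ± 0.34 and Stra8 at least 9.4-fold, and recombination genes for 7 of 11 (adjusted p = 8.19e-07), with Spata22 at least 11.8-fold and the hotspot methyltransferase gene Prdm9 at 3.76 ± 0.44. DNA replication genes were higher for 5 of 13 (adjusted p = 2.94e-04), with the cyclin genes Ccnd1 at 3.82 ± 0.48 and Ccne1 at 2.20 ± 0.25. The largest female excesses were those of Sct (at least 54.7-fold), the homeobox gene Msx1 (5.74 ± 0.30), Gata2 (5.64 ± 0.26) and Cdx2 (at least 18.7-fold). On the X chromosome 81 genes were higher and 27 lower, or 83 and 27 adjusted over the list alone (adjusted p = 8.43e-04). Fetal male germ cell genes were lower in females for 7 of 8 (adjusted p = 2.34e-10), with Nanos2 at -5.63 ± 0.50 and Dnmt3l at least 13.3-fold lower. Spermatogonial genes were lower for 12 of 20 (adjusted p = 1.35e-08), with Egr4 at least 45.7-fold lower and Nanos3, a germ cell survival gene, at -4.16 ± 0.30. Pluripotency genes were lower for 12 of 19 (adjusted p = 1.35e-08), with Nanog at -2.77 ± 0.37 and Pou5f1 at -1.59 ± 0.27. Glycolysis genes were lower for 5 of 12 and higher for 1 (adjusted p = 3.42e-03, and adjusted p = 1.31e-01 with an estimated correlation), and Y-linked genes were lower for 4 of 5 (adjusted p = 5.14e-04). Median scaling gave 806 higher and 1113 lower genes, cyclic loess called 1922, and only 4 unchanged genes were called in the simulated data.

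At E14.5 limma called 3518 genes, 1741 higher and 1777 lower in females, and at E15.5 it called 4401, 2103 higher and 2298 lower. All 7 meiotic axis genes were higher in females at E14.5 (adjusted p = 1.91e-06), with Stra8 at least 9.8-fold, Hormad2 at 3.64 ± 0.28 and Rec8 at 3.40 ± 0.34. A day later 5 were higher and 1 lower (adjusted p = 6.90e-03, and adjusted p = 1.93e-01 with an estimated correlation). The lower gene was Rec8 (-1.77 ± 0.34), and Stra8 was then below background in both sexes, while Smc1b (3.85 ± 0.29) and the transverse filament gene Sycp1 (2.83 ± 0.34) were higher. Recombination genes were higher for 9 of 11 and lower for 1 at E14.5 (adjusted p = 1.91e-06) and higher for 10 at E15.5 (adjusted p = 2.58e-05). Among them, Prdm9 stood at 5.10 ± 0.44 and 4.24 ± 0.44 on these days, and Msh5, which stabilizes crossovers, at least 13.7-fold and at least 18.3-fold higher. Other female excesses at E14.5 were those of the zinc finger gene Zfp672 (6.30 ± 0.38), Msx1 (at least 36.7-fold) and the meiotic gene M1ap (5.52 ± 0.32). At E15.5 the largest was that of Id1, an inhibitor of helix-loop-helix factors (at least 41.6-fold), beside Inca1 (at least 36.3-fold) and the guidance ligand gene Slit2 (at least 27.6-fold). Xist was at least 2.8-fold higher in females at E15.5 on its brightest probe, while another did not pass (0.84, adjusted p = 7.79e-02). DNA replication genes were higher in females for 6 of 13 and lower for 1 at E14.5 (adjusted p = 7.92e-03), with Rrm2 at least 4-fold.

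Male excesses on these days lay in fetal male germ cell, piRNA pathway, spermatogonial, pluripotency and glycolysis genes. All 8 fetal male germ cell genes were lower in females at E14.5 (adjusted p = 1.18e-06) and 5 at E15.5 (adjusted p = 6.90e-03). Dnmt3l differed by -7.22 ± 0.43 and -8.17 ± 0.43, the PIWI gene Piwil4 by -5.49 ± 0.42 at E14.5 and by at least 49.2-fold at E15.5, and Nanos2 by at least 49.2-fold and then at least 5.3-fold. Of 14 piRNA pathway genes 8 were lower in females on each day (adjusted p = 6.18e-03 and 2.19e-03), with Tdrd1 at -2.23 ± 0.33 and -2.84 ± 0.33. Spermatogonial genes were lower for 13 of 20 at E14.5 (adjusted p = 1.18e-06) and 11 at E15.5 (adjusted p = 2.91e-04), each with 1 higher, and included Egr4 (-6.43 ± 0.39, then at least 48.7-fold) and the homeobox gene Rhox10 (at least 35.5-fold and at least 27.7-fold). Pluripotency genes were lower for 13 and 12 of 19 (adjusted p = 1.40e-06 and 1.12e-04), with Dppa4 at -3.75 ± 0.13 and -5.26 ± 0.13 and Pou5f1 at -2.90 ± 0.27 and -3.51 ± 0.27. Glycolysis genes were lower for 6 of 12 at E14.5 (adjusted p = 2.95e-03, and adjusted p = 9.52e-02 with an estimated correlation) and 7 at E15.5 (adjusted p = 7.84e-05), with the hexokinase gene Hk2 at -3.39 ± 0.38 and -3.64 ± 0.38. Y-linked genes were lower for 3 of 5 at E14.5, or 4 adjusted over the list alone (adjusted p = 3.96e-03), with Usp9y at least 11.7-fold lower. At E15.5 median scaling gave 782 higher and 2004 lower genes, and cyclic loess called 2656 genes, after 2883 at E14.5.

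From E16.5 to E18.5, limma called 4879 genes between the sexes at E16.5 (2204 higher and 2675 lower in females), 4812 at E17.5 (2290 and 2522) and 4735 at E18.5 (2226 and 2509). Id1 led in females at 7.36 ± 0.23 and 7.55 ± 0.23, and at E18.5 by at least 101.9-fold. Single genes joined it, while the oocyte list did not pass at E16.5 (adjusted p = 4.27e-01) or E17.5 (adjusted p = 6.89e-02). Among the single genes were the oocyte transcription factor genes Figla (5.36 ± 0.33 at E16.5) and Lhx8 (6.07 ± 0.26 at E17.5 and 6.02 ± 0.26 at E18.5) and Ccno, a cyclin (5.32 ± 0.25 at E17.5 and 5.83 ± 0.25 at E18.5). At E18.5 the list was higher for 15 of 16 (adjusted p = 2.85e-08), with the maternal effect gene Nlrp5 at 6.17 ± 0.25 and Padi6 at 5.56 ± 0.46, and Trp63, which guards oocytes against DNA damage, stood at 6.19 ± 0.38. Dppa3, an early germ cell gene, was lower in females at E14.5 (-3 ± 0.20) and E15.5 (-4.06 ± 0.20) and higher from E16.5 (2.58 ± 0.20) to E18.5 (5.79 ± 0.20). Recombination genes were higher in females for 9 of 11 at E16.5 (adjusted p = 3.77e-04, and adjusted p = 5.45e-02 with an estimated correlation) and 8 at E17.5 (adjusted p = 3.59e-04), with Tex11 at 3.84 ± 0.26 and 3.13 ± 0.26. The reference Spo11 was higher in females at E16.5 (1.62 ± 0.19) and lower at E18.5 (-1.63 ± 0.19).

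Dnmt3l remained far higher in males from E16.5 on (at least 81.2-fold, at least 214.6-fold and at least 168.5-fold). Piwil4 (-4.28 ± 0.42 at E17.5 and -3.48 ± 0.42 at E18.5), the metallothionein gene Mt1 (-7.49 ± 0.31 and -7.45 ± 0.31), the tektin gene Tekt1 (at least 46.1-fold at E17.5) and Rsph1 (at least 43.6-fold at E17.5) were also lower in females. Glycolysis genes were lower in females for 7 of 12 at E16.5 (adjusted p = 3.77e-04, and adjusted p = 1.54e-01 with an estimated correlation), 11 at E17.5 (adjusted p = 1.05e-05) and all 12 at E18.5 (adjusted p = 1.50e-07). The glucose transporter gene Slc2a3 was at least 10.7-fold lower, then -4.60 ± 0.36 and at least 37.5-fold lower. Pluripotency genes were lower for 9 of 19 and higher for 1 at E17.5 (adjusted p = 8.83e-03, and adjusted p = 1.16e-01 with an estimated correlation) and at E18.5 (adjusted p = 8.48e-03, and adjusted p = 1.32e-01 with an estimated correlation), with Sall4 at -4.78 ± 0.44 at E18.5. Beside these, Sertoli markers were lower in females for 10 of 13 at E18.5 (adjusted p = 7.65e-04, and adjusted p = 1.68e-01 with an estimated correlation), with Clu at least 21.5-fold and Inha at least 7.8-fold lower. Endothelial markers were lower for 5 of 7 (adjusted p = 3.68e-02, and adjusted p = 2.62e-01 with an estimated correlation), with the VEGF receptor gene Flt1 at least 15.8-fold lower on its brightest probe. Another Flt1 probe stood at -0.77, which is under 2-fold. At E16.5 median scaling, which moved the median by -0.319 log2, gave 147 higher and 3275 lower genes, and cyclic loess called 2360 genes. Cyclic loess gave 1428 higher and 2068 lower genes at E17.5 and 1321 and 2003 at E18.5. In simulated data with the spread of the E16.5 arrays 385 unchanged genes were called, against 17 at E17.5 and 2 at E18.5.

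Averaged over the 7 days (14 arrays against 14), 2918 genes differed between the sexes, 1296 higher and 1622 lower in females. The single genes named next were ranked only among the 287 of these whose female and male arrays did not overlap. Larger mean differences can therefore exist among the other genes. Id1 (5.75 ± 0.09), Zfp672 (4.48 ± 0.14), Id3 (3.43 ± 0.08), the X-linked respiratory gene Ndufa1 (3.40 ± 0.08) and Slit2 (3.32 ± 0.09) led in females. Egr4 (-6.01 ± 0.15), Rhox10 (-4.96 ± 0.12), Vstm2l (-4.78 ± 0.12), Rsph1 (-4.73 ± 0.10), the Sertoli defensin gene Defb19 (at least 9-fold) and the adaptor gene Grb7 (-4.32 ± 0.09) led in males. Meiotic recombination genes were higher in females for 10 of 11 (adjusted p = 2.24e-05) and meiotic axis genes for 5 of 7 (adjusted p = 3.79e-03, and adjusted p = 1.66e-01 with an estimated correlation). Lower in females were 11 of 19 pluripotency genes (adjusted p = 2.24e-05), 7 of 8 fetal male germ cell genes (adjusted p = 1.64e-04), 10 of 20 spermatogonial genes (adjusted p = 7.38e-04), 10 of 12 glycolysis genes (adjusted p = 1.37e-05) and 6 of 13 Sertoli markers (adjusted p = 0.01, and adjusted p = 2.14e-01 with an estimated correlation). For 8250 genes, 75.4% of those tested, the sex difference itself changed between days (limma F-test). Median scaling gave 595 higher and 1153 lower genes for the mean, and cyclic loess called 1713 in all.

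**Figure D1:**
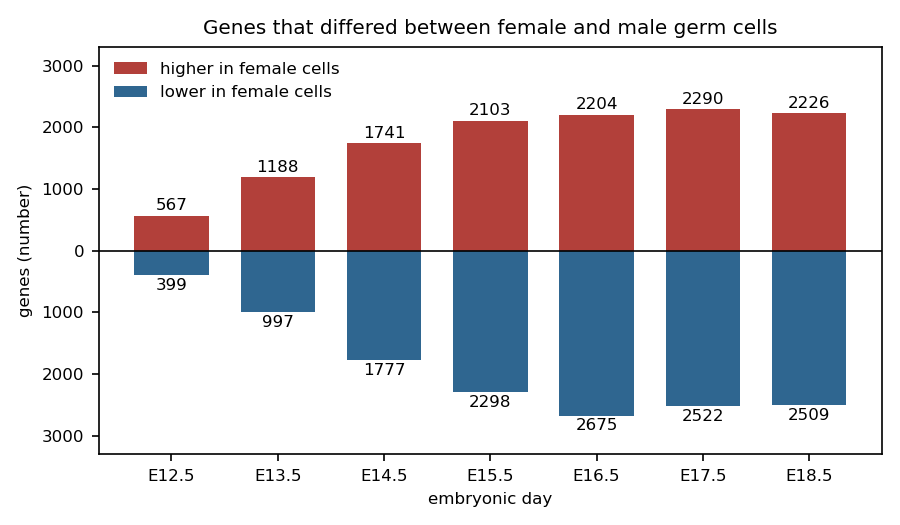
Number of genes called higher (up) or lower (down) in female than in male PGC at each embryonic day, 2 arrays against 2 per day. The count grows from 966 at E12.5 to 4879 at E16.5, whereas with cyclic loess it goes from 460 at E12.5 to 2883 at E14.5 and 2360 at E16.5.

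Female PGC enter meiosis between E12.5 and E16.5, and these days were compared directly (2 arrays against 2). Oocyte and recombination genes rose, and early germ cell, pluripotency, replication and glycolysis genes fell. Sohlh1, a transcription factor of early oocytes and spermatogonia, rose at least 168.9-fold, Nlrp5 at least 26.3-fold, the meiotic cyclin gene Ccnb3 at least 23.2-fold, Lhx8 at least 15.1-fold and Figla by 5.44 ± 0.33. The oocyte list rose for 7 of 16 and fell for 2 (adjusted p = 1.09e-02, and adjusted p = 1.05e-01 with an estimated correlation). Recombination genes rose for 8 of 11 and fell for 1 (adjusted p = 1.68e-05), with Spata22 at least 15.2-fold, Msh5 at least 3.1-fold and Spo11 by 2.45 ± 0.19. Sycp1 rose at least 2.8-fold, while Rec8 fell at least 9.6-fold. The meiotic axis list did not pass, and its mean went from 8.51 log2 at E12.5 to 10.05 at E14.5 and 8.04 at E16.5. Recombination genes averaged 7.53 at E12.5, 10.22 at E15.5 and 9.28 at E16.5, so the end days miss a rise and fall between them. Early germ cell genes fell for 12 of 13 (adjusted p = 6.53e-09), with Tfap2c, a factor of PGC specification, at least 20.4-fold and the interferon-induced gene Ifitm3 at least 21.8-fold. Pluripotency genes fell for 15 of 19 (adjusted p = 1.09e-08), with Pou5f1 at least 22.8-fold, Esrrb at least 14.5-fold and Sall4 by 5.29 ± 0.44. DNA replication genes fell for 12 of 13 (adjusted p = 1.90e-09), with the helicase gene Mcm7 at least 10.1-fold and Ccnd1 at -4.01 ± 0.48. Mitosis genes fell for 6 of 9 (adjusted p = 7.39e-04), with Cdc20 by 2.51 ± 0.15 and Plk1 by 2.13 ± 0.24. Glycolysis genes fell for 9 of 12 (adjusted p = 7.83e-05), with Slc2a3 at least 8.4-fold. Phlda2 fell at least 32.4-fold and the pyruvate dehydrogenase gene Pdha1 at least 15.3-fold, while Tktl1, a transketolase relative, rose by 5.35 ± 0.23, the flagellar gene Morn5 at least 31.4-fold and Hba-a1 by 4.94 ± 0.80. Ddx4 fell at least 4.7-fold on its brightest probe, which is treated in the closing section. Limma called 3727 genes, 1764 higher and 1963 lower, and 331 unchanged genes were called in the simulated data. Median scaling, with a shift of -0.424 log2, gave 65 higher and 3845 lower genes and turned the mitochondrial respiration list, which otherwise did not pass, to a fall (adjusted p = 3.00e-02), and cyclic loess called 1561.

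**Figure D2:**
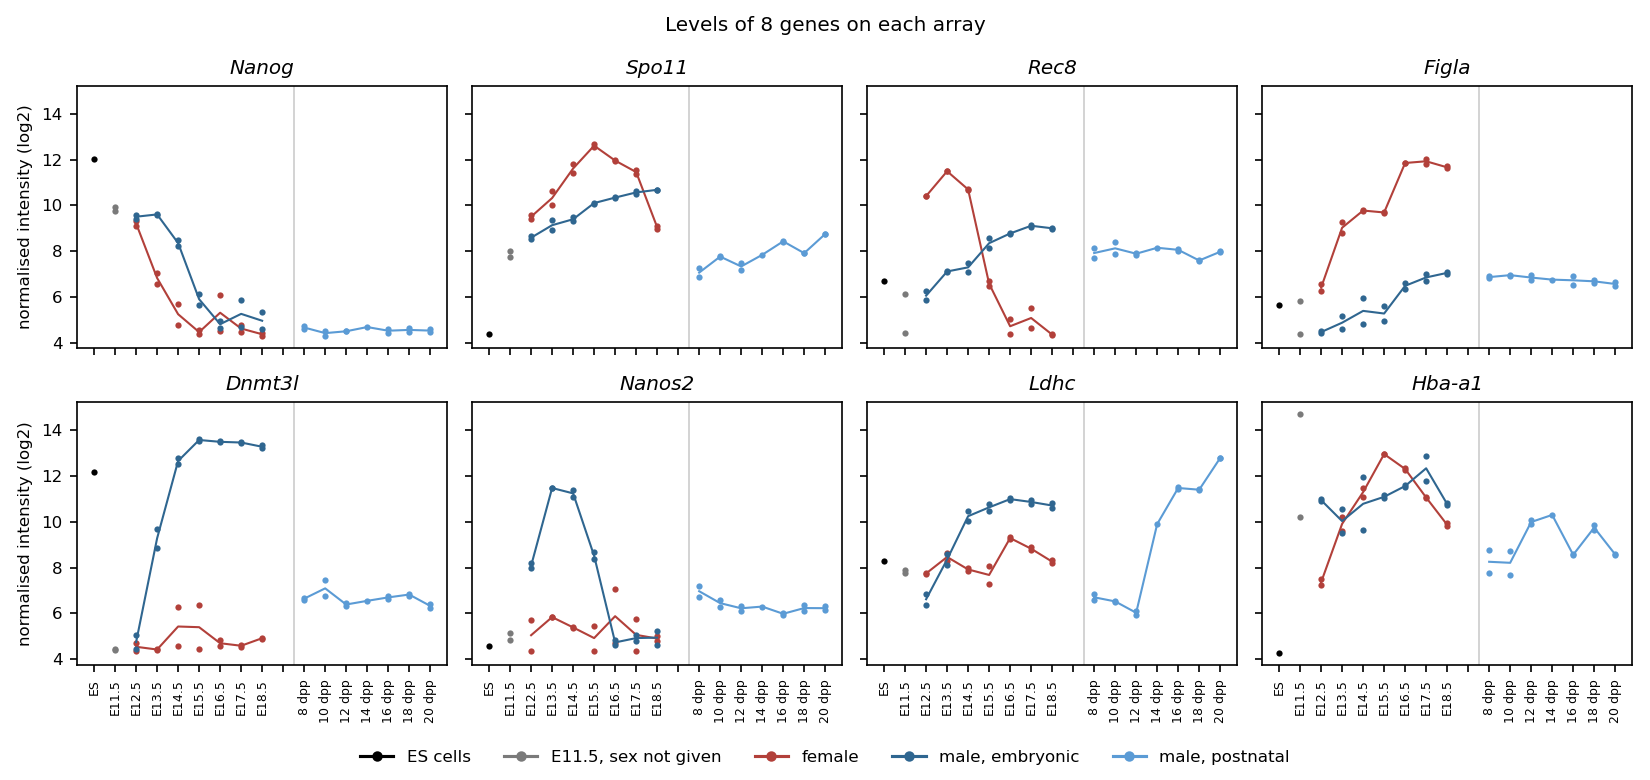
Normalized log2 intensity of 8 genes on each array (points) with group means (lines), for ESC, E11.5, female and male PGC by embryonic day and males by day after birth. Figla stands higher in females, Dnmt3l stands higher in males from E13.5, and Ldhc rises after birth.

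From E16.5 to E18.5 female cells gained more oocyte transcripts (2 arrays against 2). Of 16 oocyte genes 12 rose and 0 fell (adjusted p = 7.47e-10), with Padi6, a component of the egg's cytoplasmic lattices, at least 29.9-fold, the growth factor gene Gdf9 at least 9.2-fold, Nlrp14 at least 7.6-fold and the zona pellucida gene Zp3 at least 2-fold. Dppa3 rose by 2.82 ± 0.20 and Pou5f1 at least 10.3-fold, while Spo11 fell by 2.91 ± 0.19. The mitochondrial gene Nipsnap2 (at least 7.3-fold) and the anchoring protein gene Akap12 (at least 9.8-fold) also rose, and with E17.5 in place of the dim E16.5 arrays their rises were 2.11 and 1.56. The rises of the RNA-binding protein genes Hnrnpa2b1 (5.59 ± 0.43) and Hnrnpa1 (at least 6.6-fold) and the dynein light chain gene Dynll2 (at least 7.4-fold) rest on low values of the E16.5 arrays, which lay below both E15.5 and E17.5. With E17.5 as the start they were 0.92, 0.65 and 0.22 and did not pass, nor did another probe of Hnrnpa2b1 (1.03) and of Hnrnpa1 (0.75). The neuropeptide gene Pth2 (at least 13.7-fold), the synapsin gene Syn1 (at least 8.6-fold), the class II antigen gene H2-Ab1 (at least 7.7-fold), the glycine cleavage gene Gldc (at least 5.9-fold) and Gadd45g, a stress response gene (-3.65 ± 0.39), fell. DNA replication genes rose for 6 of 13 and fell for 1 (adjusted p = 3.32e-02, and adjusted p = 5.97e-02 with an estimated correlation), with Mcm7 at least 1.3-fold and Tyms by 2.10 ± 0.22. With cyclic loess that list and Mcm7 turned, and another Tyms probe gave -1. Limma called 2812 genes, 1481 higher and 1331 lower, and 314 unchanged genes were called in the simulated data. Median scaling, with a shift of 0.479 log2, gave 4144 higher and 5 lower genes, cyclic loess called 1358, the 4 compared arrays alone 1528, and E17.5 in place of the dim E16.5 arrays 904.

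Male PGC stop dividing between E12.5 and E16.5 (2 arrays against 2). Dnmt3l and genes of the piRNA pathway rose, and replication, mitosis and early germ cell genes fell. Dnmt3l rose at least 199.7-fold and Sohlh1 at least 116.9-fold. Of 14 piRNA pathway genes, 9 rose and 0 fell (adjusted p = 2.93e-04), with Piwil4 at 5.46 ± 0.42, the piRNA methyltransferase gene Henmt1 at least 5.3-fold and Tdrd6 at least 4.5-fold. Gonadal germline genes rose for 6 of 10 and fell for 1 (adjusted p = 1.31e-02, and adjusted p = 1.79e-01 with an estimated correlation), with Tex101 at least 8.9-fold, Taf7l by 3.90 ± 0.18 and Tex11 at -2.75 ± 0.26. Rises were also seen for the cilium genes Tekt1 (at least 39.2-fold) and Ccdc113 (at least 24.1-fold), the phosphatase gene Dusp26 (at least 30-fold), the peptidase gene Dpep3 (at least 22.3-fold) and Ldhc, the sperm lactate dehydrogenase (4.37 ± 0.21). Mitosis genes fell for 6 of 9 (adjusted p = 1.10e-05), with the kinesin gene Kif11 at -4.01 ± 0.25, Birc5 at -3.52 ± 0.19 and Cdk1 at -3.40 ± 0.19. DNA replication genes fell for 11 of 13 (adjusted p = 1.36e-06), with Tyms by 3.65 ± 0.22 and Ccne1 at least 7.1-fold. Histone genes H3c6 (at least 43.7-fold), H3c1 (at least 24.2-fold) and H2ac21 (at least 21.9-fold) fell as well. Early germ cell genes fell for 10 of 13 (adjusted p = 1.05e-05), with Ifitm3 by 5.50 ± 0.32 and Dppa3 by 4.94 ± 0.20. Pluripotency genes fell for 11 of 19 and rose for 2 (adjusted p = 3.01e-04), with Lefty1 at least 53.3-fold, Nanog at least 20-fold and Sox2 at -4.11 ± 0.36. Pou5f1 did not pass (-0.25 ± 0.27). Nanos2 fell at least 7.4-fold. Some markers of other cell types rose over this step without their lists passing, with 5 of 7 endothelial (adjusted p = 7.66e-02), 2 of 6 granulosa (adjusted p = 2.62e-01) and 2 of 10 mesenchymal markers, beside 1 that fell (adjusted p = 8.01e-01). Limma called 4271 genes, 2299 higher and 1972 lower, against 1232 and 1597 under median scaling and 2670 in all with cyclic loess.

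For the last days before birth in males (E18.5 against E16.5, 2 arrays against 2), limma called 715 genes, 401 higher and 314 lower, and no gene list passed. Largest rises were those of the antibody receptor subunit gene Fcer1g (at least 6.1-fold), the homeobox genes Otx2 (2.91 ± 0.29) and Irx3 (2.84 ± 0.40), Sall2 (2.67 ± 0.31), the cyclin gene Ccnd2 (2.52 ± 0.66), the clock gene Bhlhe40 (2.44 ± 0.38) and the collagen cross-linking gene Lox (at least 3.1-fold). Largest falls were those of the actinin gene Actn2 (-2.82 ± 0.48), the neuropeptide gene Kiss1 (at least 5.1-fold), the sperm channel gene Catsperd (-2.58 ± 0.36), Svs4 (-2.72 ± 0.46), the steroid enzyme gene Cyp17a1 (at least 3.6-fold) and Spidr, a DNA repair gene (-2.10 ± 0.24). Fcer1g, Irx3 and Cyp17a1 belong to the macrophage, granulosa and steroidogenic marker lists. From E16.5 to E18.5 in males the means of these lists went from 4.6 to 5.9, 5.99 to 6.42 and 5.95 to 4.82 log2. A source of these changes in other cells among those sorted was not tested. Dnmt3l (-0.21 ± 0.43), Piwil4 (-1.04 ± 0.42) and Pou5f1 (0.28 ± 0.27) did not pass. Median scaling gave 350 higher and 21 lower genes with a shift of 0.114 log2, cyclic loess 207 and 72, and no background correction 55 and 27. The 4 compared arrays alone gave 308 genes.

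Across birth, from E18.5 to 8 dpp, mitosis and DNA replication genes rose in male cells, and Dnmt3l and glycolysis genes fell (2 arrays against 2). Mitosis genes rose for 6 of 9 (adjusted p = 2.51e-04), with Plk1 at 3.39 ± 0.24 and Birc5 at 2.74 ± 0.19. DNA replication genes rose for 10 of 13 (adjusted p = 1.84e-05), with Cdc6 at 4.53 ± 0.25, Tyms at 2.83 ± 0.22 and Mcm2 at 2.30 ± 0.14. Stra8 rose at least 22.2-fold, Tex11 by 5.12 ± 0.26, the tubulin regulator Stmn1 by 4.60 ± 0.25, the cold-inducible gene Cirbp by 4.47 ± 0.25, the abscission gene Cep55 at least 12.1-fold and the centriole kinase gene Plk4 by 3.85 ± 0.59. Nanos2 rose by 2.02 ± 0.50 and Sycp1 by 1.33 ± 0.34. Dnmt3l fell by 6.63 ± 0.43 and Ldhc fell by 4.01 ± 0.21. Falls also came for Spo11 by 3.62 ± 0.19, Piwil4 by 2.60 ± 0.42 and Pou5f1 by 2.41 ± 0.27. The largest falls were joined by the myosin gene Myh8 (at least 44.1-fold), the cadherin gene Cdhr1 (at least 27.7-fold), the flagellar gene Spag6l (at least 22.6-fold), Tekt1 (-5.19 ± 0.36), the zinc transporter gene Slc39a4 (-5.06 ± 0.29), the protease gene Hpn (at least 18.5-fold) and the integrin gene Itga11 (at least 24-fold). Glycolysis genes fell for 7 of 12 (adjusted p = 1.14e-02, and adjusted p = 1.99e-01 with an estimated correlation), with Ldha at -3.45 ± 0.19 and Pfkp at -3.52 ± 0.38. Beside them, endothelial markers fell for 5 of 7 (adjusted p = 1.89e-02, and adjusted p = 2.04e-01 with an estimated correlation), with Flt1 by 3.98 ± 0.19. Ddx4 fell by 2.29 ± 0.41 on its brightest probe and was 1.46 higher on another, so its direction is open. Limma called 4101 genes, 2021 higher and 2080 lower. Median scaling, with a shift of 1.10 log2, gave 5706 higher and 990 lower genes, and cyclic loess, with a shift of -0.179, gave 1204 and 2221.

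The first wave of spermatogenesis was tested as 16 to 20 dpp (6 arrays) against 8 to 10 dpp (4 arrays). Spermatocyte genes rose for 9 of 12 and fell for 0 (adjusted p = 1.01e-32). Ldhc rose by 5.27 ± 0.14, Pgk2, a glycolytic kinase of spermatocytes, at least 2.1-fold, the acrosome gene Dkkl1 by 1.78 ± 0.22, the RNA-binding gene Ybx2 by 1.60 ± 0.10 and the meiotic cyclin gene Ccna1 by 1.03 ± 0.24. Of 14 piRNA pathway genes 2 rose (adjusted p = 6.17e-05), Tdrd6 at least 11.5-fold and Piwil1, the PIWI protein of pachytene cells, by 1.31 ± 0.18. Further rises were those of Clec2m (at least 9.4-fold), the nucleotide synthesis gene Prps1l1 (at least 6.4-fold), the flagellar genes Spag6l (at least 6.9-fold) and Rsph1 (3.38 ± 0.16), the protease inhibitor gene Spink2 (3.24 ± 0.17), Adam32 (at least 5.6-fold) and Tcp10a (at least 5.5-fold). Of the spermatid genes used as references, Prm1 lay below background at both ages and Tnp1 did not pass (-0.34 ± 0.22). Gonadal germline genes passed as a list with 0 of 10 members past the threshold (adjusted p = 4.07e-02, and adjusted p = 3.61e-01 with an estimated correlation). Falls were small and took in the ERK phosphatase gene Dusp6 (-1.62 ± 0.18), the gap junction gene Gja1 (-1.59 ± 0.35), Tcl1 (-1.43 ± 0.18), the activin subunit gene Inhbb (-1.29 ± 0.29), Egr2 (-1.28 ± 0.18) and Nefm (at least 1.7-fold). Sertoli markers fell for 2 of 13, or 4 adjusted over the list alone (adjusted p = 7.27e-05, and adjusted p = 8.16e-02 with an estimated correlation), namely Dhh (-1.47 ± 0.26) and Aard (-1.16 ± 0.23). Mesenchymal markers fell as a list with 0 of 10 members past the threshold (adjusted p = 2.46e-02, and adjusted p = 4.14e-01 with an estimated correlation). Genes of the X chromosome, which is silenced in male meiosis, fell for 4 of 381 and rose for 0 (adjusted p = 9.64e-03). Their mean moved little, from 6.95 and 6.91 log2 at 8 and 10 dpp to 6.86, 6.78 and 6.83 at 16, 18 and 20 dpp. Whether silencing lies behind this small shift was not tested. Limma called 139 genes, 110 higher and 29 lower, against 155 and 76 under median scaling with a shift of -0.108 log2 and 222 in all with cyclic loess. For 20 dpp against 8 dpp it called 198 higher and 10 lower.

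Whether both sexes change alike at meiosis was asked as the female change from E12.5 to E16.5 minus the male change from 8 to 10 dpp to 16 to 20 dpp. These sides share no arrays. Meiotic axis genes averaged 7.15 log2 in E18.5 males but already 8.51 at 8 dpp, and 8.52 at 20 dpp. Recombination genes averaged 7.64 at 8 dpp and 7.85 at 20 dpp. The male side thus need not span the same stages of meiosis as the female side. Differences between the sides can come from stage as well as from sex, and these were not told apart. The changes differed for 3618 genes, 1721 in favour of females and 1897 in favour of males, and for 1992 of them at least 1 of the groups lay below the background. Recombination genes stood higher in the female change for 8 of 11 and lower for 0 (adjusted p = 2.01e-05), with Spata22 at least 11.7-fold. Oocyte genes were higher for 6 of 16 and lower for 1, or 6 and 2 adjusted over the list alone (adjusted p = 2.03e-02, and adjusted p = 1.65e-01 with an estimated correlation), with Sohlh1 at least 160.1-fold, Nlrp5 at least 29.1-fold and Figla at 5.69 ± 0.39. Ccnb3 (at least 28.7-fold), Tktl1 (5.42 ± 0.28), the secretion gene Cadps2 (at least 17-fold) and Ccno (4.85 ± 0.30) also led. The female change was more negative for 14 of 19 pluripotency genes (adjusted p = 2.73e-08), 12 of 13 early germ cell genes (adjusted p = 2.49e-09), 11 of 13 DNA replication genes (adjusted p = 2.49e-09), 6 of 9 mitosis genes (adjusted p = 1.05e-03) and 8 of 12 glycolysis genes, or 9 adjusted over the list alone (adjusted p = 2.06e-05). The starting levels differed, with early germ cell genes at 9.84 log2 in E12.5 females and already 6.08 at 8 dpp. Pluripotency genes stood at 9.28 and 7.32. Male cells had less to lose in these lists, so the contrast there mainly restates the female fall. Rsph1 was lower in the female change at least 31.3-fold, Slc2a3 at least 38.5-fold, Phlda2 at least 35.6-fold, Mcm7 at least 13.1-fold and Tfap2c at least 20.3-fold, and Ldhc differed by -3.73 ± 0.25. Among genes called in each change, 35 rose in both, among them Ldhc, Piwil1, Ybx2, Morn5 and Nme5, where 17.7 would be shared by chance (Fisher's exact test, two-sided, p = 3.83e-05). Only 6 fell in females and rose in males, among them Ldha, Slc2a3 and Rsph1, where chance gives 19.7 (exact p = 2.31e-04). Those that fell in both numbered 9 against 5.2 (exact p = 0.0855), and 5 rose in females and fell in males against 4.7 (exact p = 0.802). Among the 7022 genes detected in both changes, a choice made after seeing the data, 26 rose in both against 7 by chance (exact p = 2.17e-11), while the 6 that fell in females and rose in males no longer differed from chance, at 9.9 (exact p = 0.196). Median scaling, with a shift of -0.412 log2, gave 105 higher and 3385 lower genes, and cyclic loess called 1864. In the simulated data 170 unchanged genes were called.

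Some lists never passed in any comparison. The lowest adjusted p was 3.22e-01 for apoptosis genes (E12.5 against E11.5), 1.15e-01 for mitochondrial respiration and 1.68e-01 for immediate early and heat shock genes (both in the same comparison) and 2.39e-01 for cyclin-dependent kinase inhibitors (female against male at E18.5). It was 2.62e-01 for spermatid genes (males, E16.5 against E12.5), 1.56e-01 for granulosa markers (males, 8 dpp against E18.5), 1.80e-01 for steroidogenic cell markers (16 to 20 against 8 to 10 dpp) and 6.14e-02 for macrophage markers (males, E18.5 against E16.5). With an estimated correlation 73 of the 101 passing lists still passed.

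**Figure D3:**
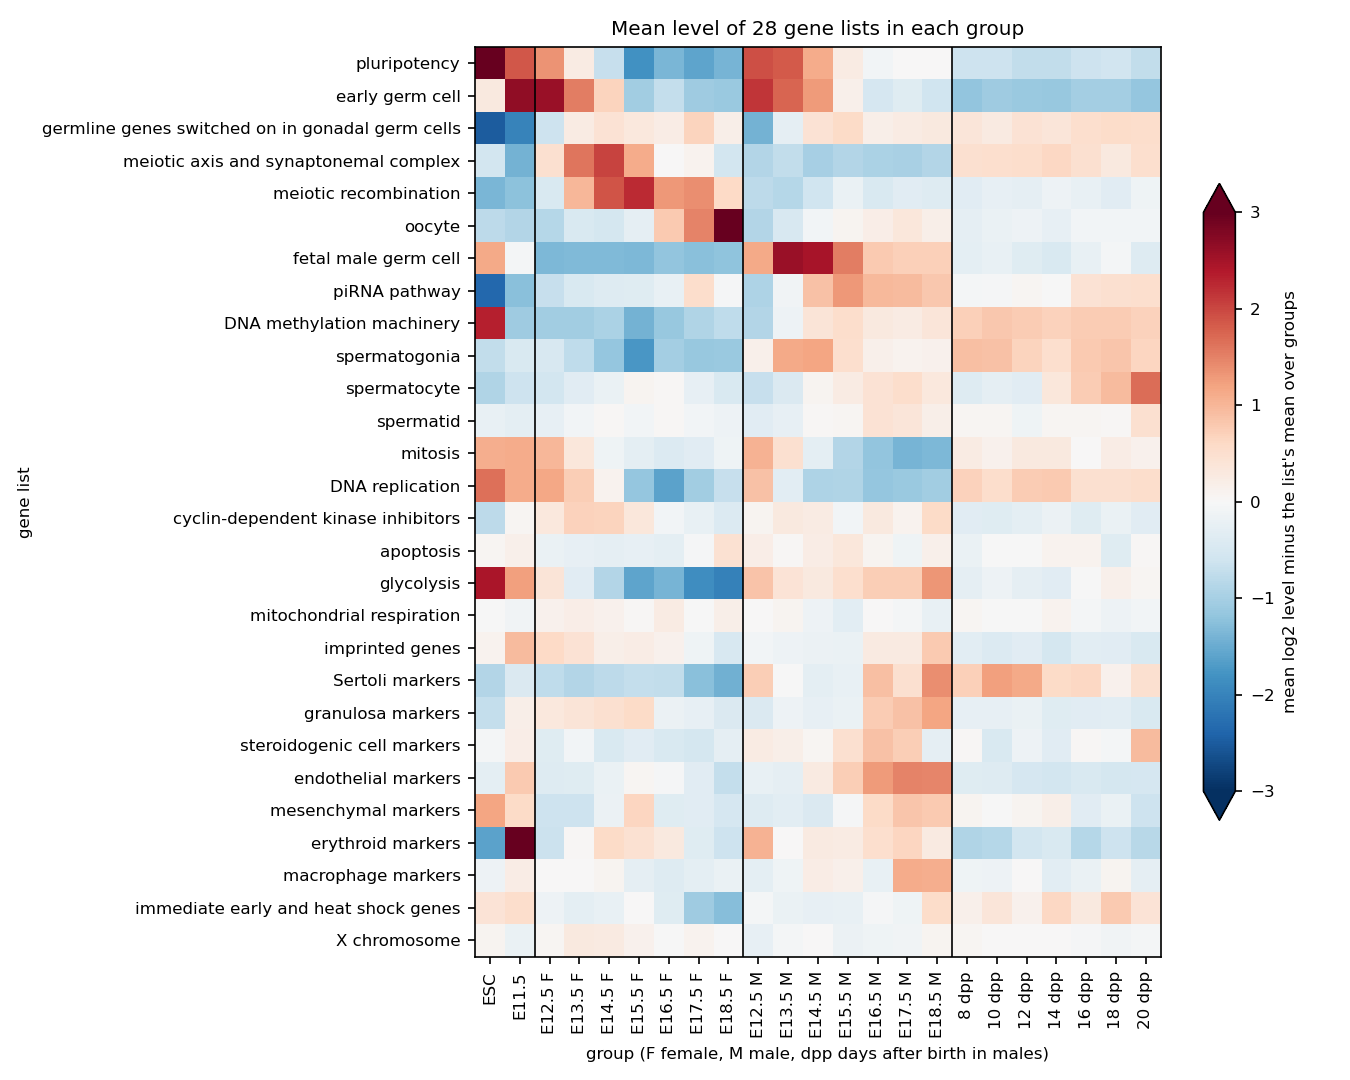
Mean log2 intensity of each gene list in each group minus the mean of that list over all groups, in colour, with lists as rows and groups as columns. Pluripotency genes average 10.94 in ESC and 6.54 in E18.5 females, and oocyte genes 5.75 and 9.76.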

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

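Of the tests in this part, the one on genes that rose across birth and the splits by whole groups were chosen only after the result was seen. The test of different changes in the sexes, with its E17.5 end day, was chosen after the lists were tested. No group held as many as 4 arrays, so no single array was tested against its group.

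The change of meiotic recombination genes from E12.5 to E16.5 differed between the sexes, with a mean of 1.76 log2 in females and 0.31 in males over 11 genes, a difference of 1.45 (adjusted p = 7.68e-03 for the difference itself, adjusted p = 2.11e-01 with an estimated correlation, and 1.42 with E17.5 as the end day). The change of glycolysis genes over these days differed too, with -1.76 in females and -0.11 in males over 12 genes, a difference of -1.65 (adjusted p = 4.73e-02, adjusted p = 6.11e-01 with an estimated correlation, and -2.13 with E17.5 as the end day). Ldhc stood at 9.90 log2 on the single 14 dpp array, a day in no comparison, which is 3.07 above the highest array of 8 to 10 dpp at 6.83.

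For the mean sex difference, labels were exchanged among the 28 arrays in a model of day and label, and 1 of the 100 splits, the real one, called as many genes as the real labels did. It called 2907 genes, the highest other split 1327 and the next 1. Chance can thus be excluded only if the arrays of a pair count as separate samples. With the arrays of each group kept together and the sexes exchanged within days, 1 of 64 splits, the real one, called as many (2907, highest other 2737). A labelling by whole groups that was wrong on at least 1 day thus called nearly as many genes. Some of these splits exchange the sexes on a single day and keep all other days right. Which split gave 2737 is not known, so the count does not show how labellings wrong on more days would fare. For 16 to 20 against 8 to 10 dpp, 1 of the 100 splits, the real one, called as many (126, highest other 2), and chance can be excluded there too if the arrays of an age count as separate samples, as the series states and its protocol leaves open. By whole age there are 10 splits, too few for a share under 0.05 (126, highest other 1).

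Across birth in males, 2080 genes fell and 2021 rose while the upper quartile of intensity went from at most 124.8 at E18.5 to several times that at 8 dpp. Of the falls, 36.8% (766 genes) were detected on both dim E18.5 arrays and on neither bright 8 dpp array. A loss of detections on dim arrays alone would not give this. Detection did not follow brightness here, though, as the shares of detected probes below show. A technical source of these falls is therefore not excluded. For the rises, dim arrays cannot be told apart from a change in the cells. Of 322 risen genes that were detected at 8 dpp alone, 31.7% (102) were detected at no higher a level on both arrays of another embryonic group no brighter than E18.5, so that dim arrays could in principle show them. At any level 56.5% of them were detected in such a group. The E18.5 arrays also detected more probes (48.4% and 49.3%) than those of 8 dpp (43.5% and 44.8%). A change with age stays open and was not tested apart from brightness.

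In E16.5 female cells 1012 genes differed the same way from E15.5 and from E17.5, where the highest other day and sex gave 201. Of these, 634 were lower, and 79.2% of them (502) were detected on neither E16.5 female array, which are the dimmest of the series, so low brightness is a candidate explanation for most of the falls. A change of the cells on that day is not excluded. Among the 378 that were higher, 2.9% (11) were detected on both E16.5 female arrays and on none of the neighbouring days, which is too few to tell. Ddx4 is an example of the falls, since its brightest probe fell at least 4.7-fold from E12.5 to E16.5 and its other probes did not pass (-0.33, adjusted p = 4.47e-01, and -0.04, adjusted p = 9.11e-01).

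Marker genes of other cell types were measured in the sorted cells, and their source is open. The replicate differences of 13 Sertoli markers had a mean correlation of 0.27 over 13 male groups, against a median of 0 and a 95th percentile of 0.07 for random lists (one-sided permutation p = 1e-04, the smallest that 10000 random lists can give), which may come from RNA of Sertoli cells. Clu stood at 10.30 and Cst9 at 9.68 log2 at E18.5 in males. Erythroid markers gave 0.8 over 15 embryonic groups (6 markers, random median -0.01, one-sided permutation p = 1e-04, the smallest possible), and Hba-a1 reached 12.96 in E15.5 females and Hbb-y 12.42 at E11.5, so RNA of red blood cells is a candidate source that the FACS sort would be set to remove. Endothelial markers gave 0.28 (7 markers, one-sided permutation p = 0.0014) and mesenchymal markers 0.3 (9 markers, one-sided permutation p = 3e-04) over these groups, so they varied together too, while granulosa markers did not, with 0.01 (5 markers, one-sided permutation p = 0.4405). Expression of these genes by the germ cells was not tested.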

How the results depend on the processing

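Alternatives that leave out or replace the E16.5 female arrays, and those for the overlap at meiosis, were chosen only after the result was seen, and all others were planned. Of the counts of genes under alternatives other than leaving out an array, 179 stayed within 1.5 times the reported count, 56 were lower by more and 11 higher by more. Of values of named genes, 4009 kept direction and side of the threshold, 144 lost the call, 6 gained it and 8 turned, and of list results 1131 kept theirs, 57 lost it, 123 gained it and 4 turned. With an array left out 2926 gene values kept theirs, 27 lost it and 1 turned, and 889 list results kept theirs, 15 lost it and 18 gained it. No count moved by more than 1.5 times with the authors' values, each probe on its own, no filter, detection on at least 4 arrays, a trend with a robust prior or a replicate block. Without the filter, however, the larger direction turned in some comparisons. Higher and lower genes were then 2850 and 2653 for female vs male E16.5 and 2298 and 1952 for female E16.5 vs E12.5. They were 1485 and 1852 for female E18.5 vs E16.5, 2178 and 1862 for female meiosis vs male meiosis and 1852 and 1855 for embryonic PGC vs ESC. Replicate numbers do not pair the samples in general (correlations of replicate differences over 210 pairs of groups from -0.12 to 0.33, median 0.01). Of these pairs 21 lay above 0.1 and 3 below -0.1, so a shared structure in some groups is not excluded. The replicate block gave 664 genes for E12.5 vs E11.5. A slide block was not run because the files give no slide. Without the E16.5 day 2675 genes were called for the mean sex difference and 7754 for sex by day. Dim arrays limit what can be seen near the background. Where values below differ from those reported, the cause was not tested.

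No background correction gave 1485 genes for embryonic PGC vs ESC, 33 for E12.5 vs E11.5, 161 for female vs male E12.5, 707 at E13.5, 1437 at E14.5, 2009 at E15.5, 2260 at E16.5, 2119 at E17.5, 2032 at E18.5 and 940 for the mean. It gave 1408 for female E16.5 vs E12.5, 735 for female E18.5 vs E16.5, 1751 for male E16.5 vs E12.5, 82 for male E18.5 vs E16.5, 1571 for male 8 dpp vs E18.5, 29 for male 16 to 20 dpp vs 8 to 10 dpp and 1469 for female meiosis vs male meiosis. An offset of 50 gave, in the same order, 1879, 55, 226, 912, 1794, 2464, 2796, 2681, 2563 and 1256, and then 1826, 1086, 2261, 144, 2001, 44 and 1895.

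Cyclic loess gave 68 for E12.5 vs E11.5, 460 for female vs male E12.5, 2656 at E15.5, 2360 at E16.5, 1713 for the mean, 1561 for female E16.5 vs E12.5, 1358 for female E18.5 vs E16.5, 2670 for male E16.5 vs E12.5, 279 for male E18.5 vs E16.5, 222 for male 16 to 20 dpp vs 8 to 10 dpp and 1864 for female meiosis vs male meiosis. Median scaling gave 333 for E12.5 vs E11.5, 340 for female vs male E12.5, 2786 at E15.5, 1748 for the mean, 2829 for male E16.5 vs E12.5, 371 for male E18.5 vs E16.5, 6696 for male 8 dpp vs E18.5 and 231 for male 16 to 20 dpp vs 8 to 10 dpp. No fold threshold gave 1452 for E12.5 vs E11.5, 1798 for female vs male E12.5, 3606 at E13.5, 7951 for the mean, 4387 for female E18.5 vs E16.5, 1725 for male E18.5 vs E16.5 and 353 for male 16 to 20 dpp vs 8 to 10 dpp. The compared arrays alone gave 0 for E12.5 vs E11.5 (limma, 1921 at an unadjusted p under 0.05 on 6 arrays), 590 for female vs male E12.5, 1528 for female E18.5 vs E16.5 and 308 for male E18.5 vs E16.5. For E12.5 vs E11.5, array weights gave 217, E12.5F alone 1096, and leaving out each array 278 to 1660, the lowest without E11.5 replicate 1 and the highest without E11.5 replicate 2. E17.5 in place of E16.5 gave 904 for female E18.5 vs E16.5. In the overlap at meiosis it gave 9 genes lower in females and lower in males, now above chance (exact p = 8.02e-03), and turned those higher in females and lower in males to 0, below chance (exact p = 2.66e-02). Only genes detected in both changes gave 9 lower in females and lower in males, now above chance (exact p = 2.68e-02), and 6 lower in females and higher in males, no longer different from chance (exact p = 0.196).

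Reversed with E11.5 alone against ESC were the mitosis list (adjusted p = 9.00e-01, now up), Sox2 (0.01), Spata22 (-0.13) and Tex101 (-0.33). For E12.5 vs E11.5, the fetal male germ cell list went up with E12.5M alone (adjusted p = 6.23e-05), Phlda2 was 1.04 with E12.5F alone and Igf2 ran from -2.39 without E11.5 replicate 2 to 0.12 without E11.5 replicate 1. Cyclic loess turned the DNA replication list (adjusted p = 9.51e-01, now down) and Mcm7 (-0.02) for female E18.5 vs E16.5, where another Tyms probe gave -1. Median scaling turned mitochondrial respiration (adjusted p = 3.00e-02, now down) and Uhrf1 (-0.71) for female E16.5 vs E12.5. Another Ddx4 probe gave 1.46 for male 8 dpp vs E18.5. For 27 of 344 gene values in the text, at least 1 other probe of the gene differed in call or direction.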

Other observations

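All tests named in this part were planned, apart from the test of different changes in the sexes, which was chosen after the lists were tested.

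Neither the DNA methylation list nor that of cyclin-dependent kinase inhibitors passed a test of different changes in the sexes from E12.5 to E16.5 (adjusted p = 8.36e-01 and 7.56e-01), and the values that follow are those of single genes. Uhrf1, which guides maintenance methylation, rose from E12.5 to E16.5 in females (1.14 ± 0.19) and fell in males (-1.98 ± 0.19), and it rose in males across birth (2.90 ± 0.19). Its female rise turned to -0.71 under median scaling, and another, dimmer Uhrf1 probe did not pass there (0.29, adjusted p = 3.39e-01). The de novo methyltransferase gene Dnmt3b rose in males before E16.5 (1.72 ± 0.16) and again across birth (2.51 ± 0.16), where it stood at 12.50 ± 0.03 log2 (SD, 2 arrays), near the 12.79 of the ESC array. Before E16.5 another, dimmer Dnmt3b probe did not pass in males (0.34, adjusted p = 3.89e-01). Cdkn1c, an imprinted inhibitor of the cell cycle, rose in males from E12.5 to E16.5 (1.86 ± 0.28) and fell across birth (-3.67 ± 0.28). Cdkn2a rose in the former step too (1.05 ± 0.19), while Cdkn1a fell by 2.49 ± 0.40 in males and at least 2.9-fold in females.

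After birth, spermatocyte genes averaged 6.19 log2 at 8 dpp, 6.31 at 10 dpp, 6.23 at 12 dpp, 6.92 at 14 dpp, 7.35 at 16 dpp, 7.54 at 18 dpp and 8.25 at 20 dpp. Spermatid genes averaged 5 to 5.19 from 8 to 18 dpp and 5.61 at 20 dpp. Spermatogonial genes averaged 8.22 at 8 dpp, 7.84 at 14 dpp, 8.17 at 18 dpp and 7.98 at 20 dpp, with no steady course.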
